A study of Rattus norvegicus with 9 samples.

How the data were processed

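Total RNA from rat liver was measured on 9 one-colour oligonucleotide arrays, 3 in each of 3 groups that the sample titles name Sham-Sham, Sham-CLP and Burn-CLP. The labels give a number from 1 to 3 within each group and do not say whether arrays of a group came from separate animals, so every p-value measures only the spread between these samples, which may be technical. The deposited values are intensity values on a linear scale, 1 per probe set and array, for 15923 probe sets. How they were made from the scanned images is not given in the sources used here. The values show that each array had been scaled to a common level, because the mean after trimming 2% at each end lay between 499.76 and 499.81 on all 9 arrays. Values of 57 control probe sets were left out of the tests. Arrays have no read depth, and their number limits the precision.

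The choices that follow were made before the data were examined, except where stated. The deposited scaling was to be kept if all array medians lay within 10% of their mean. Sham-Sham 1 had a median of 117.55% of that mean and Sham-CLP 2 one of 89.9%, so the arrays were quantile normalized and the deposited scaling became an alternative. The medians lay between 89.9% and 93.1% in Sham-CLP and between 101% and 103% in Burn-CLP, a difference that the normalization also removed. Signals below the 20th percentile of all values, a signal of 64.3, were set to that floor, and log2 was taken. A probe set was tested if at least 3 of the 9 arrays lay above the floor, which left 13535 probe sets. A fold change against a group with all 3 arrays at the floor is a lower bound and is given as "at least", computed from the mean log2 signal of the other group and the floor. For called genes with only some arrays of a group at the floor their number is given, and the fold understates the change. Among genes given as values without passing, Klf4, Klf10, Per2, Cd37, Bdh1, Gstt1, Myc, S100a8, Alox5ap, Sult2a2, Igfals and Rnf213 also have 1 or 2 arrays of a compared group at the floor.

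Gene names came from the platform annotation supplied with the series and were updated to the symbols of the GRCr8 RefSeq annotation, through the Entrez identifier for 12748 probe sets and through an accession for 2, while 33 kept the supplied symbol. In all, 12783 probe sets had 1 symbol, 312 had several and 2771 had none. Among the tested probe sets 11121 had 1 symbol, for 9339 genes. No probe set with several symbols was named. Members of gene families such as ribosomal proteins, cytochromes P450, MHC molecules and glutathione transferases are named as annotated, and cross-hybridization between them was not excluded. No genome coordinates are given because probe positions were not used here.

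Each pair of groups was compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on 1 fit of all 9 arrays, with a moderated F test over the 3 groups. Benjamini-Hochberg adjusted p-values under 0.05 over the 13535 probe sets were called. Values are log2 changes with their standard error (SE) from this fit, and mean signals with the standard deviation (SD) over 3 arrays. With 3 arrays against 3, an exact permutation test of a single gene cannot give a two-sided p under 0.1, so none was used for single genes. For 34 gene lists fixed in advance, which covered the acute phase response, metabolism, stress responses, hormone responses and markers of other liver and blood cell types, camera tested the shift against the other genes with a preset correlation of 0.01, using for each gene the probe set with the highest mean. Adjustment was over the 34 lists. The alternatives were a correlation estimated from the data, and fry, which tests whether the members move on balance in 1 direction without comparing them with other genes. For each list the members past the threshold are counted with adjustment over all probe sets tested and with adjustment over the list alone.

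Named genes are, for each comparison, the 12 largest rises and the 12 largest falls among called probe sets with 1 symbol whose groups did not overlap. Where fewer than 10 probe sets passed, the 10 with the smallest p are given as values. Each list with 2 or more called members or a called shift adds up to 4 members with the smallest p, and each marker list its 2 brightest members. Genes named outside this rule are said to have been chosen after their values were seen.

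The steps were tested on simulated data with the spread of these arrays, 13535 probe sets and 200 of them changed in the simulated Burn-CLP group. In the simulated Burn-CLP against Sham-Sham comparison, 35% of changes of log2 1 and 93% of changes of log2 2 were recovered, with 8 false calls among 136. In the simulated Burn-CLP against Sham-CLP comparison the shares were 42% and 92%, with 4 false calls among 138. None of 34 unchanged lists was called (0 lists) and a planted list was, with an adjusted p of 9.41e-13, or 0.00926 with an estimated correlation. The simulated genes varied independently of each other, so this checks the steps but not the preset correlation of 0.01. In the real data the estimated correlation ran from -0.028 (tricarboxylic acid cycle) to 0.471 (cholesterol synthesis). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

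The alternatives were the deposited scaling, floors at the 5th and 40th percentile, no filter, a filter of 6 arrays above the 40th percentile, the replicate number as a block, array weights, eBayes with a trend and robust prior, only the 2 groups compared, 1 probe set per gene, an added 2-fold threshold, and each array left out in turn. A further 2 were added after the data were seen, namely the deposited scaling with Sham-Sham 1 left out and counts of calls with no array of the compared groups at the floor.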

Results

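Liver RNA was compared among 3 groups of 3 arrays. By their names, Sham-Sham is a control with 2 sham procedures, Sham-CLP received CLP after a sham procedure, and Burn-CLP received a burn and CLP. The labels do not spell CLP out; in rodent injury work it stands for cecal ligation and puncture, which causes abdominal infection. The comparisons ask what CLP changed in liver, what burn with CLP changed, and whether the burned group differed from the group with CLP alone. Deposited array medians ran from 205 to 268.1 at a common trimmed mean. Sham-Sham 1 stood apart, with a mean correlation of 0.863 with the other 8 arrays, which themselves lay between 0.915 and 0.931. Sham-Sham 3 correlated at 0.9407, 0.9445 and 0.9508 with the Sham-CLP arrays, but at 0.8665 and 0.9269 with Sham-Sham 1 and Sham-Sham 2. The 5S ribosomal RNA control probe set read 68.2, 112 and 157.8 in Sham-Sham, 153.1 to 218.5 in Sham-CLP and 185.7 to 247.4 in Burn-CLP. The 3'/5' signal ratio of Gapdh lay between 0.991 and 1.46 and that of beta-actin between 1.15 and 1.77 over the 9 arrays.

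Sham-CLP liver differed from Sham-Sham liver in 8 called genes. Lcn2, which encodes the iron-siderophore binding protein lipocalin 2, rose 25.2-fold (log2 change 4.66 ± 0.24 SE, n = 3 per group, adjusted p = 6.83e-05), from a mean signal of 669 ± 72.8 to 17290 ± 4761 (SD). A2m, the major acute phase protease inhibitor of the rat, rose 18.1-fold (4.18 ± 0.33, adjusted p = 0.00184). Pla2g2a, a secreted phospholipase A2 of the acute phase response, rose 11.1-fold (3.47 ± 0.32, adjusted p = 0.00398). The neurotrophin gene Ntf3 rose at least 3.46-fold and the E3 ubiquitin ligase gene Mid1 at least 2.41-fold, since all 3 Sham-Sham arrays lay at the floor for both. Smpdl3b, a gene of the sphingomyelin phosphodiesterase family, rose 2.48-fold with 2 of 3 Sham-Sham arrays at the floor. Foxo4, a forkhead transcription factor gene, fell 3.94-fold (-1.98 ± 0.26, adjusted p = 0.0422). The autophagy gene Atg2b fell at least 2.42-fold with all 3 Sham-CLP arrays at the floor, while its other probe set differed by -0.32 (adjusted p = 0.53). The next smallest p-values did not pass, with an adjusted p of 0.0553 each. They belonged to the fatty acid binding protein gene Fabp5 (1.80 ± 0.25), the procollagen processing gene Pcolce (1.60 ± 0.23) and the sterol isomerase gene Ebp (1.49 ± 0.21).

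These 8 probe sets, 6 higher and 2 lower, were all that passed of 13535. With the deposited scaling 4 passed, all 4 higher. At an unadjusted p under 0.05 there were 1587, against 677 expected by chance, and the groups did not overlap for 16.7% of probe sets, where chance gives 10%. The count was 5 without Sham-Sham 2, 347 without Sham-Sham 3, 4 without Sham-CLP 1, 5 without Sham-CLP 2 and 13 without Burn-CLP 2, an array of the third group that enters through normalization, floor, filter and the shared spread. Calls of Lcn2, A2m and Ntf3 held in the alternatives followed gene by gene, 16 for Ntf3, which the stricter filter left out, and 17 for the others, and that of Pla2g2a without each array in turn. Smpdl3b lost its call without Sham-Sham 2 (adjusted p = 0.0924), Sham-CLP 1 (0.12), Sham-CLP 2 (0.149) or Sham-CLP 3 (0.0607). Foxo4 lost it without Sham-Sham 1 (0.1), Sham-Sham 2 (0.157), Sham-CLP 1 (0.267), Sham-CLP 2 (0.199), Sham-CLP 3 (0.0646), Burn-CLP 1 (0.0698) or Burn-CLP 3 (0.0737). Mid1 and Atg2b lost theirs without any 1 array but Sham-Sham 3, with adjusted p up to 0.267 for Sham-CLP 1.

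Genes of cholesterol synthesis had the largest list shift in Sham-CLP. The median log2 change of the 20 measured genes was 1.18 (adjusted p = 3.39e-13, camera), with an adjusted p = 0.492 with an estimated correlation. None (0 genes) passed over all probe sets tested, while adjusted over the list alone 16 rose and 1 fell. Among the members, Lss (lanosterol synthase) differed by 2.05 ± 0.40, Ebp by 1.49 ± 0.21, Cyp51 (lanosterol demethylase) by 1.15 ± 0.27 and Pmvk (phosphomevalonate kinase) by 0.97 ± 0.18. The member that fell over the list alone was Insig2 (-0.82 ± 0.27), an endoplasmic reticulum protein that retains the sterol sensor; it was named after its value was seen. The list kept its call without each array in turn, with medians from 0.96 to 1.54.

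The acute phase list, 34 genes of proteins known to rise in inflammation, shifted upward with a median of only 0.12 (adjusted p = 0.00154), which was 0.06 without Sham-Sham 1 and up to 0.16 without another array. The adjusted p was 0.492 with an estimated correlation. With the deposited scaling the median over 1 probe set per gene was -0.075 in this comparison, and relative to it the list stood at 0.41 (adjusted p = 4.10e-11). In it 2 genes rose, Lcn2 and A2m, and 5 rose adjusted over the list alone. Spink1, a trypsin inhibitor gene, differed by 3.36 ± 0.53 (adjusted p = 0.0838) and Lbp, the lipopolysaccharide binding protein gene, by 0.86 ± 0.22. The glucocorticoid response list shifted upward by a median of 0.56 over 17 genes (adjusted p = 5.53e-05; adjusted p = 0.501 with an estimated correlation). No member (0) passed over all probe sets, and 5 rose adjusted over the list alone; the aspartate aminotransferase gene Got1 differed by 1.37 ± 0.21, the tryptophan dioxygenase gene Tdo2 by 0.61 ± 0.18, the orosomucoid gene Orm1 by 0.56 ± 0.15 and the clock gene Per2 by 1.13 ± 0.35. Of these 17 genes 10 also stood in other lists, and the list's median was 0.36 without Sham-Sham 3 and, relative to all genes, 0.85 with the deposited scaling.

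Fatty acid oxidation genes shifted downward in Sham-CLP, with a median of -0.32 over 38 genes (adjusted p = 0.000662; adjusted p = 0.776 with an estimated correlation) and 0 members passing, over all probe sets or adjusted over the list alone. Acot2, an acyl-CoA thioesterase gene, differed by -1.38 ± 0.40, the enoyl-CoA isomerase gene Eci1 by -0.81 ± 0.26, Etfdh by -0.61 ± 0.16 and the carnitine acetyltransferase gene Crat by -0.58 ± 0.18. With the deposited scaling the median relative to all genes was -0.10 and this call was lost (adjusted p = 0.408). Lipogenesis genes shifted upward by a median of 0.16 over 24 genes (adjusted p = 0.0337; adjusted p = 0.776 with an estimated correlation). No lipogenesis gene (0) passed over all probe sets and 2 rose adjusted over the list alone; Acaca (acetyl-CoA carboxylase) differed by 0.78 ± 0.17, Acly (ATP citrate lyase) by 1.16 ± 0.35, Pgd by 0.62 ± 0.16 and Lpin1 by 1.09 ± 0.37. The lipogenesis call was lost without Sham-Sham 2, Sham-Sham 3 or Sham-CLP 3, with adjusted p up to 0.158, and was kept with the deposited scaling (adjusted p = 0.00251; median 0.14 relative to all genes).

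Amino acid breakdown genes shifted upward by a median of 0.13 over 42 genes (adjusted p = 0.0198; adjusted p = 0.776 with an estimated correlation), a call lost without Sham-Sham 3 or Sham-CLP 2 with adjusted p up to 0.529; the median was 0.06 without Sham-Sham 3, 0.21 without Sham-CLP 3 and, relative to all genes, 0.40 with the deposited scaling (adjusted p = 1.52e-07). Bhmt differed by 1.12 ± 0.31, Oat by 1.11 ± 0.32, Tdo2 by 0.61 ± 0.18 and Acmsd by 0.93 ± 0.31, and 0 members passed, adjusted over the list alone or not. Immediate early genes shifted upward by a median of 0.28 over 25 genes (adjusted p = 0.0242; adjusted p = 0.492 with an estimated correlation), lost without Sham-Sham 2, Sham-Sham 3 or Sham-CLP 2 with adjusted p up to 0.0852 but kept with the deposited scaling (adjusted p = 0.0307; median 0.26 relative to all genes). Klf4 differed by 1.03 ± 0.28, Dusp1 by 1.01 ± 0.40, Klf10 by 1.06 ± 0.56 and Ier3 by 0.77 ± 0.42, and again 0 passed, adjusted over the list alone or not. For Klf4 and Klf10, Sham-Sham 1 lay at the floor. The other Sham-Sham arrays read 135.5 and 137.4 for Klf4 and 283.9 and 362.3 for Klf10. Lymphocyte markers shifted downward by a median of -0.20 over 24 genes (adjusted p = 0.0374; adjusted p = 0.492 with an estimated correlation), with 0 members passing either way. The natural killer cell genes Klrb1b and Klrd1 differed by -1.37 ± 0.44 and -0.62 ± 0.20, each with 2 of 3 Sham-CLP arrays at the floor, Cd37 by -0.54 ± 0.19 and Cd5 by -0.63 ± 0.24; the 2 brightest members, Lck and Il2rb, differed by -0.27 ± 0.21 and -0.20 ± 0.21. That call was lost without Sham-Sham 1, 2 or 3, Sham-CLP 2 or Burn-CLP 2, with adjusted p up to 0.149, and the median was -0.30 without Sham-Sham 3. The call was kept with the deposited scaling (adjusted p = 0.00589; median -0.298 relative to all genes).

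In all, 8 of 34 lists shifted in Sham-CLP, 6 upward and 2 downward, and 0 with an estimated correlation; by fry the smallest adjusted p was 0.0712, for the acute phase list. The count of lists was 4 without Sham-Sham 3, 5 without Sham-CLP 2 and 16 with the deposited scaling. With the main scaling, markers of other cells showed no called shift here apart from the lymphocyte list. Relative to all genes under the deposited scaling, endothelial markers stood at -0.22 and macrophage markers at 0.23. The further lists called under that scaling are not named here. The brightest markers differed by -0.01 ± 0.15 (Ctsb) and 0.03 ± 0.30 (Cd14) for macrophages, -0.65 ± 0.28 (Kdr) and 0.43 ± 0.34 (Lyve1) for endothelium, and -0.26 ± 0.22 (Col3a1) and -0.04 ± 0.18 (Sparc) for stellate cells and fibroblasts. For bile duct cells they differed by 0.04 ± 0.24 (Epcam) and 0.46 ± 0.23 (Aqp1), and for blood by -0.26 ± 0.16 (Hbb) and -0.31 ± 0.24 (Hba-a3). Neutrophil markers had a median of 0.01 over 10 genes, of which Lcn2 rose over all probe sets and 2 genes rose adjusted over the list alone. The brightest other member, Cybb, differed by 0.17 ± 0.26. S100a9 differed by 1.51 without passing over all probe sets, with 2 of 3 Sham-Sham arrays at the floor.

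**Figure D1:**
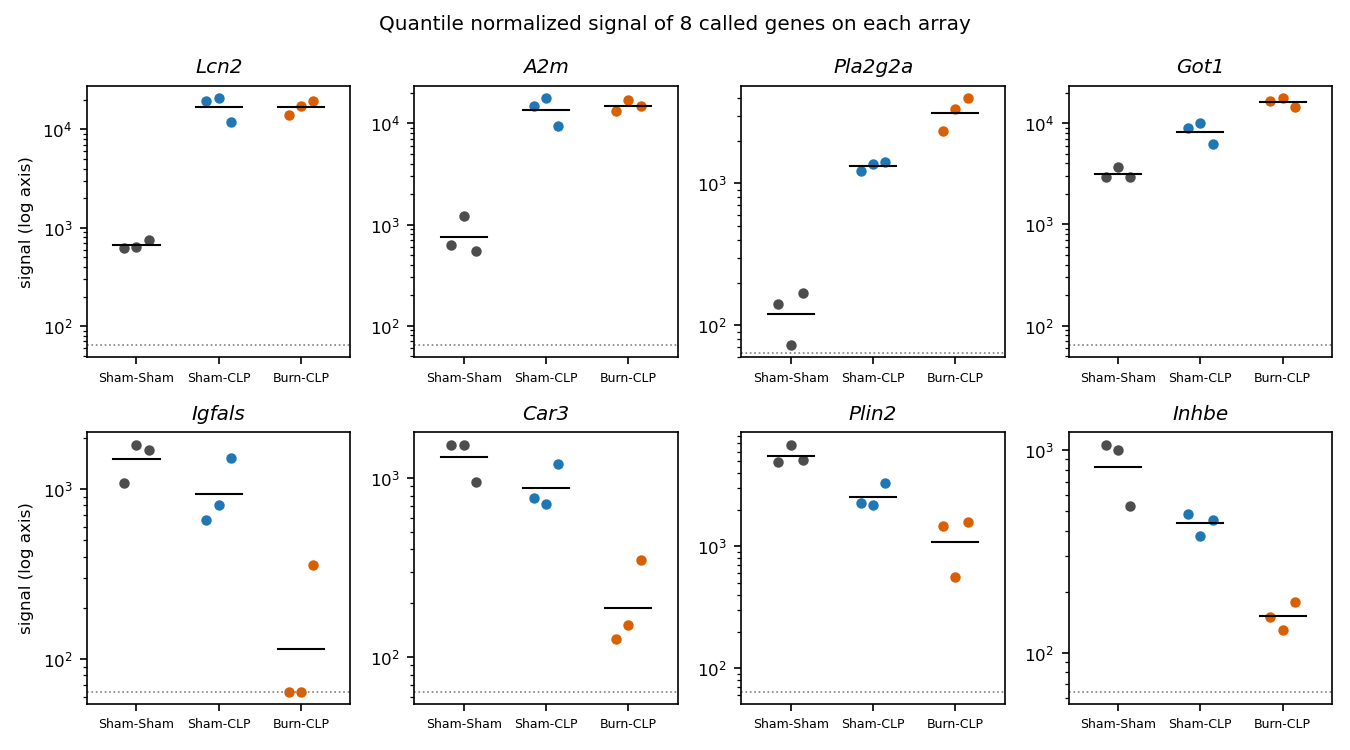
Quantile normalized signal (log axis, arbitrary units) of 8 called genes on each of the 3 arrays per group; bars are means of log2 values and the dotted line is the floor of 64.3, to which lower signals were raised. Lcn2 and A2m were high in both CLP groups, while Igfals and Car3 were lowest in Burn-CLP.

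Burn-CLP liver differed from Sham-Sham liver in 101 called probe sets, a number that was 13, against 8 for Sham-CLP, in fits of only the 2 groups compared. Pla2g2a rose 26.2-fold (4.71 ± 0.32, n = 3 per group, adjusted p = 0.000389), Lcn2 rose 25.2-fold (4.66 ± 0.24, adjusted p = 6.84e-05) and A2m rose 19.9-fold (4.32 ± 0.33, adjusted p = 0.000913). Igfals, which encodes the subunit that stabilises circulating insulin-like growth factor complexes, fell 13.1-fold (-3.71 ± 0.62, adjusted p = 0.0361) with 2 of 3 Burn-CLP arrays at the floor. Hsd17b2, a steroid dehydrogenase gene, fell 12.2-fold (-3.61 ± 0.58, adjusted p = 0.0351) with 1 of 3 at the floor.

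Further rises are given gene by gene, with no test of a common function. Spink1 rose 9.40-fold (3.23 ± 0.53), and its other probe sets differed by 2.47 and 1.21. S100a9, a calcium-binding protein gene of neutrophils, rose 6.95-fold with 2 of 3 Sham-Sham arrays at the floor. Single genes of amino acid handling were Sds, the serine dehydratase gene (6.88-fold, 2.78 ± 0.47), Acmsd, an enzyme gene of tryptophan breakdown (5.89-fold, 2.56 ± 0.31) and Got1 (5.04-fold, 2.33 ± 0.21). Transporters were the aromatic amino acid transporter gene Slc16a10 (7.59-fold, 2.92 ± 0.34) and the glutamate transporter gene Slc1a2 (5.64-fold, adjusted p = 0.0421). Slc16a10 had 1 and Slc1a2 had 2 of 3 Sham-Sham arrays at the floor, and the other Slc1a2 probe set differed by -0.12. The phosphatidate phosphatase gene Lpin1 rose 6.21-fold (2.63 ± 0.37), and Retreg1 and Edem1, which act in the turnover of the endoplasmic reticulum and of its misfolded proteins, rose 7.07-fold and 5.68-fold. The dimmer Retreg1 probe set differed by 1.95 without passing (adjusted p = 0.0693). Lbp rose 2.78-fold and Jund, an AP-1 subunit gene, at least 2.78-fold, with the other Jund probe set differing by 0.26.

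Among the largest falls were single genes of lipid handling, again without a test of that theme. Mgll, the monoglyceride lipase gene, fell at least 5.75-fold, while its other probe sets differed by -1.98, -0.29 and -0.04. The lipid droplet coat gene Plin2 fell 5.08-fold (-2.34 ± 0.37), with -0.70 at its dimmer probe set, and the fatty acid binding protein gene Fabp3 fell at least 4.40-fold. Nrep fell 11.9-fold (-3.57 ± 0.50), the carbonic anhydrase gene Car3 fell 6.93-fold (-2.79 ± 0.39) and Inhbe, the inhibin beta E gene, fell 5.45-fold (-2.45 ± 0.27). The brighter Car3 probe set differed by -4.12 without passing (adjusted p = 0.0538). Foxo4 fell 4.28-fold with 2 of 3 Burn-CLP arrays at the floor, and the sulfate transporter gene Slc13a4 fell 4.16-fold. Akr7a3, an aldehyde reductase gene, fell 4.01-fold, Cyp2t1 fell 3.06-fold and the glutathione transferase gene Gstm2 fell 2.28-fold. Rnf213 fell 4.82-fold at a probe set with 2 of 3 Burn-CLP arrays at the floor, and its other probe set differed by -0.12.

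In all, 101 of 13535 probe sets passed, 44 higher and 57 lower, for 87 named genes. The excess of lower calls turned around with the deposited scaling (49 higher, 43 lower) and without the filter (54 higher, 47 lower). At an unadjusted p under 0.05 there were 2689 against 677 by chance, and the groups did not overlap for 21.5% of probe sets, where chance gives 10%. Of the 101, 60 lay above the floor on all 9 arrays. The count depended on single arrays. It was 29 without Sham-Sham 1, 28 without Sham-Sham 2, 645 without Sham-Sham 3, 42 without Sham-CLP 1, 37 without Sham-CLP 2, 19 without Burn-CLP 1, 19 without Burn-CLP 2 and 221 without Burn-CLP 3. Of the 29 named genes that passed, Lcn2, A2m, Pla2g2a, Got1 and Inhbe kept their call in all 17 alternatives followed gene by gene. The number keeping it was 10 without Sham-Sham 1, 11 without Sham-Sham 2, 29 without Sham-Sham 3, 14 without Sham-CLP 1 or Sham-CLP 2, 25 without Sham-CLP 3, 11 without Burn-CLP 1, 10 without Burn-CLP 2 and 24 without Burn-CLP 3. All 29 kept their direction in those that tested them.

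The acute phase list shifted upward by a median of 0.26 over 34 genes (adjusted p = 2.41e-05; adjusted p = 0.489 with an estimated correlation), with 4 genes rising over all probe sets and 7 adjusted over the list alone. Those 4 were Lcn2, A2m, Spink1 and Lbp, and the list's median was 0.39 without Burn-CLP 1 and 0.15 without Burn-CLP 2. Plasma proteins known to fall in inflammation shifted downward by a median of -0.20 over 16 genes (adjusted p = 0.00715; adjusted p = 0.632 with an estimated correlation). Igfals fell over all probe sets and 4 genes fell adjusted over the list alone; Serpina6, the corticosteroid binding globulin gene, differed by -3.09 ± 0.63 (adjusted p = 0.0591), Afm (afamin) by -0.98 ± 0.25 and Igf1 by -0.71 ± 0.20. Their median was -0.10 without Burn-CLP 2 and -0.32 without Burn-CLP 3. The glucocorticoid response list shifted upward by a median of 0.83 over 17 genes (adjusted p = 1.34e-06; adjusted p = 0.489 with an estimated correlation), with Got1 and Sds rising over all probe sets and 11 genes adjusted over the list alone. Tdo2 differed by 0.83 ± 0.18 and Orm1 by 0.64 ± 0.15.

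Fatty acid oxidation genes shifted downward by a median of -0.49 over 38 genes (adjusted p = 1.52e-06; adjusted p = 0.549 with an estimated correlation). None (0) passed over all probe sets and 17 fell adjusted over the list alone. The medium-chain acyl-CoA dehydrogenase gene Acadm differed by -1.06 ± 0.24, Eci1 by -1.11 ± 0.26, Crat by -0.83 ± 0.18 and the ketone body enzyme gene Bdh1 by -3.80 ± 0.91, with adjusted p between 0.0686 and 0.079. Phase I drug metabolism genes shifted downward by a median of -0.32 over 51 genes (adjusted p = 0.00262; adjusted p = 0.549 with an estimated correlation). Cyp2t1 fell over all probe sets, and adjusted over the list alone 12 fell and 3 rose. Cyp2c11, the male-specific P450 gene of rat liver, differed by -3.43 ± 0.67 (adjusted p = 0.0538), Fmo1 by -1.94 ± 0.38 and Aldh3a2 by -1.20 ± 0.23. Conjugation enzyme genes shifted downward by a median of -0.30 over 34 genes (adjusted p = 0.0271; adjusted p = 0.677 with an estimated correlation), a call lost without Burn-CLP 2 (median -0.15, adjusted p = 0.206). Gstm2 fell over all probe sets, and adjusted over the list alone 5 fell and 1 rose; Gstm1 differed by -0.82 ± 0.18, Gstt1 by -1.84 ± 0.44 and Mgst3 by -0.87 ± 0.24.

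Interferon response and MHC class I genes shifted downward by a median of -0.39 over 31 genes (adjusted p = 0.000401; adjusted p = 0.549 with an estimated correlation), with 0 passing over all probe sets and 1 falling adjusted over the list alone. The proteasome activator gene Psme1 differed by -1.04 ± 0.23, the immunoproteasome gene Psmb8 by -1.03 ± 0.28, Irf3 by -0.80 ± 0.23 and Cxcl10 by -0.63 ± 0.20. Without Sham-Sham 1 the median was -0.21. Endoplasmic reticulum stress genes shifted downward by a median of -0.25 over 29 genes (adjusted p = 0.0394; adjusted p = 0.549 with an estimated correlation), with 0 passing over all probe sets and 4 falling adjusted over the list alone. Sec61b differed by -1.04 ± 0.27, Creld2 by -0.96 ± 0.23, Pdia4 by -0.85 ± 0.21 and Hyou1 by -0.61 ± 0.17. This call was lost without Sham-Sham 3 or Burn-CLP 3, with adjusted p up to 0.302 and a median of -0.14 without Burn-CLP 3, and with the deposited scaling (adjusted p = 0.0573).

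Several lists of abundant transcripts had small upward shifts with 0 members passing, adjusted over the list alone or not. Oxidative phosphorylation genes had a median of 0.22 over 41 genes (adjusted p = 0.0022; adjusted p = 0.489 with an estimated correlation), with Uqcrh at 0.53 ± 0.16, Slc25a3 at 0.49 ± 0.15, Slc25a4 at 0.72 ± 0.27 and Cox6b1 at 0.48 ± 0.18. Ribosomal protein genes had a median of 0.14 over 42 genes (adjusted p = 0.0237; adjusted p = 0.677 with an estimated correlation), lost without Sham-Sham 2 or Burn-CLP 2 with adjusted p up to 0.164 (median 0.08 without Burn-CLP 2). Rpl27 stood at 0.45 ± 0.15, Rpl12 at 0.45 ± 0.16, Rpl21 at 0.50 ± 0.20 and Rps6 at 0.33 ± 0.14. Proteasome and ubiquitin genes had a median of 0.18 over 24 genes (adjusted p = 0.0286; adjusted p = 0.687 with an estimated correlation), lost without Sham-Sham 2 or Burn-CLP 1 with adjusted p up to 0.349 (median 0.05 without Burn-CLP 1 and 0.29 without Burn-CLP 3). Ube2d2 stood at 0.69 ± 0.21, Psma3 at 0.53 ± 0.18, Psmc1 at 0.55 ± 0.22 and Psma7 at 0.38 ± 0.16. Macrophage markers had a median of 0.33 over 19 genes (adjusted p = 0.0415; adjusted p = 0.677 with an estimated correlation), lost without Sham-Sham 2, Burn-CLP 2 or Burn-CLP 3 with adjusted p up to 0.431 (median 0.16 without Sham-Sham 2 and 0.18 without Burn-CLP 2). Ctss stood at 0.99 ± 0.25, Csf1r at 1.02 ± 0.32, Lyz2 at 0.73 ± 0.28 and Cd14 at 0.65 ± 0.30, while Ctsb, 1 of the 2 brightest, stood at -0.15 ± 0.15.

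Urea cycle genes shifted upward by a median of 0.42 over 7 genes (adjusted p = 0.0415; adjusted p = 0.549 with an estimated correlation), with 0 passing over all probe sets and 2 rising adjusted over the list alone. Asl differed by 0.96 ± 0.25, the ornithine carrier gene Slc25a15 by 0.96 ± 0.29, Cps1 by 0.48 ± 0.17 and Arg1 by 0.42 ± 0.17. The urea cycle call was lost without Sham-Sham 1, Sham-Sham 3, Burn-CLP 1 or Burn-CLP 2, with adjusted p up to 0.141. Neutrophil markers shifted upward by a median of 0.31 over 10 genes (adjusted p = 0.0271, or 0.549 with an estimated correlation). Of these, 6 had a positive and 4 a negative change, with a mean of 0.88 and an SD of 1.63. Lcn2 and S100a9 rose, 2 genes over all probe sets and 2 adjusted over the list alone; S100a8 differed by 1.10 ± 0.42, Alox5ap by 0.66 ± 0.27 and Cybb by 0.56 ± 0.26. That call was lost without Sham-Sham 3 or Burn-CLP 2, with adjusted p up to 0.219. The neutrophil median was 0.55 without Sham-Sham 2, 0.13 without Sham-Sham 3, 0.19 without Burn-CLP 2 and 0.54 without Burn-CLP 3. Immediate early genes shifted upward by a median of 0.27 over 25 genes (adjusted p = 0.0475; adjusted p = 0.549 with an estimated correlation), with Jund rising over all probe sets and 2 genes adjusted over the list alone. Klf4 differed by 1.24 ± 0.28, Gadd45b by 2.19 ± 0.99 and Myc by 1.49 ± 0.72, with Sham-Sham 1 at the floor for Klf4 and Myc. Their call was lost without any 1 of the Sham-Sham arrays 1, 2 and 3, Burn-CLP 1 or Burn-CLP 2, with adjusted p up to 0.165 (median 0.43 without Burn-CLP 3), and with the deposited scaling (adjusted p = 0.062).

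In all, 15 of 34 lists shifted in Burn-CLP against Sham-Sham, 9 upward and 6 downward, and 0 with an estimated correlation. By fry 4 lists passed, namely the acute phase (adjusted p = 0.00782), oxidative phosphorylation (0.0175), neutrophil (0.0217) and glucocorticoid (0.0217) lists. Lcn2 belongs to both the acute phase and the neutrophil list, so those calls are not independent. Amino acid breakdown genes had a median of 0.05 (adjusted p = 0.197), with Sds and Acmsd rising over all probe sets and, adjusted over the list alone, 5 rising and 1 falling; Kynu differed by -0.93 ± 0.20. Cholesterol synthesis genes had a median of 0.44 (adjusted p = 0.142) and lipogenesis genes of -0.17 (adjusted p = 0.142). The brightest markers of other cells differed by -0.48 ± 0.22 (Col3a1), 0.03 ± 0.18 (Sparc), -0.76 ± 0.28 (Kdr), 0.62 ± 0.34 (Lyve1), 0.11 ± 0.24 (Epcam), 0.78 ± 0.23 (Aqp1), -0.41 ± 0.16 (Hbb), -0.61 ± 0.24 (Hba-a3), 0.16 ± 0.21 (Lck) and -0.19 ± 0.21 (Il2rb).

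**Figure D2:**
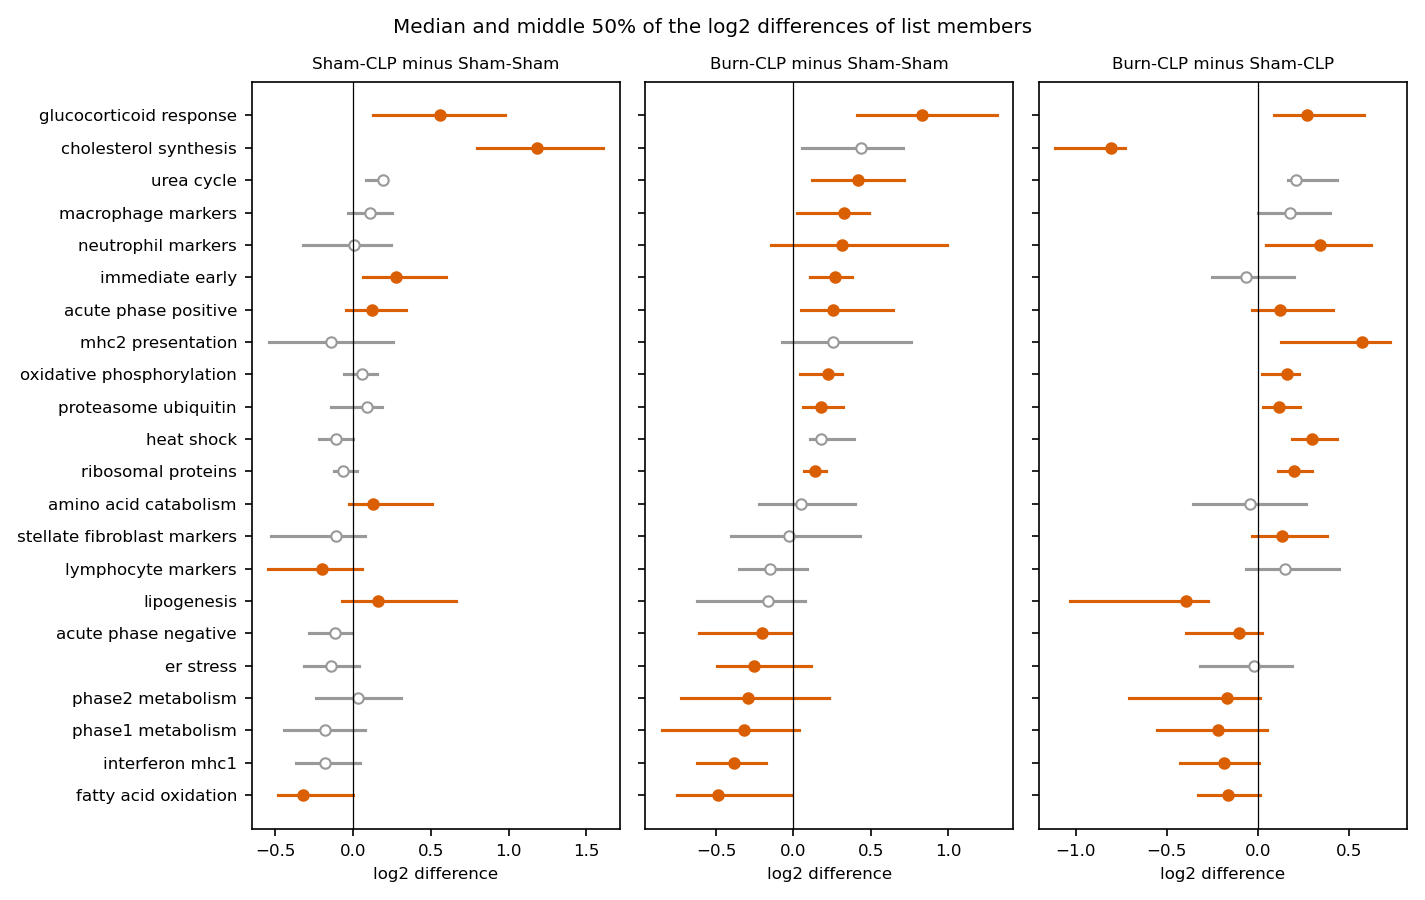
Median (dot) and middle 50% (line) of the log2 differences of list members for the 22 gene lists called in at least 1 comparison; filled orange marks an adjusted camera p under 0.05 with the preset correlation of 0.01, open grey the others; with an estimated correlation 0 lists were called in any comparison. Cholesterol synthesis genes had a median of 1.18 in Sham-CLP against Sham-Sham and -0.81 in Burn-CLP against Sham-CLP; with the deposited scaling the acute phase list turned to -0.08 in the latter, and oxidative phosphorylation, ribosomal protein and proteasome lists fell below the shift of all genes.

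Burn-CLP and Sham-CLP liver differed in 2 called genes, neither of which kept its call without each array in turn. Lrrc51, a leucine-rich repeat gene, rose 3.17-fold in Burn-CLP over Sham-CLP (1.66 ± 0.15, n = 3 per group, adjusted p = 0.0124), with 2 of 3 Sham-CLP arrays at the floor. Sult2b1, a sulfotransferase gene for cholesterol and other sterols, rose at least 3.06-fold (1.62 ± 0.18, adjusted p = 0.0361), with all 3 Sham-CLP arrays at the floor. Other small p-values did not pass. Dcn, the decorin gene, differed by 1.40 ± 0.21 (adjusted p = 0.131), Tcp11l2 by 1.16 ± 0.17 (0.131), the cytochrome b5 reductase gene Cyb5r3 by -1.12 ± 0.17 (0.131) and Rnf213 by -1.81 ± 0.23 (0.0613). Tmed1 differed by -1.69 ± 0.25 with all 3 Burn-CLP arrays at the floor, at least 3.22-fold lower. A further 3 of the 10 smallest p-values belonged to probe sets without a symbol, with log2 differences of -1.52 ± 0.18 (adjusted p = 0.0521), -0.997 ± 0.156 and 0.91 ± 0.14. At an unadjusted p under 0.05 there were 1231 probe sets against 677 by chance, and the groups did not overlap for 18.8%, where chance gives 10%. The count was 1 without Sham-Sham 1 or Sham-Sham 2, 9 without Sham-Sham 3, 0 without any 1 Sham-CLP array, 0 without Burn-CLP 1 or Burn-CLP 2 and 36 without Burn-CLP 3. Lrrc51 lost its call without Sham-CLP 1 (adjusted p = 0.164), Sham-CLP 2 (0.073), Sham-CLP 3 (0.123), Burn-CLP 1 (0.0901) or Burn-CLP 2 (0.105), and Sult2b1 without these (adjusted p up to 0.223) or Sham-Sham 1 (0.0567) or Sham-Sham 2 (0.0996). With the deposited scaling 1 passed, and with no array allowed at the floor 0.

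Lipid synthesis genes were lower in Burn-CLP than in Sham-CLP as lists. Cholesterol synthesis genes shifted downward by a median of -0.81 over 20 genes (adjusted p = 2.00e-09; adjusted p = 0.463 with an estimated correlation), with 0 passing over all probe sets and 3 falling adjusted over the list alone. The sterol dehydrogenase gene Nsdhl differed by -1.69 ± 0.35, the sterol reductase gene Tm7sf2 by -1.25 ± 0.21, Pmvk by -0.98 ± 0.18 and Ebp by -0.65 ± 0.21. Lipogenesis genes shifted downward by a median of -0.40 over 24 genes (adjusted p = 3.51e-06; adjusted p = 0.463 with an estimated correlation), and adjusted over the list alone 7 fell and 1 rose, with 0 over all probe sets. The elongase gene Elovl5 differed by -1.27 ± 0.29, Acly by -1.32 ± 0.35, Acsl3 by -0.97 ± 0.25 and Lpin1 by 1.54 ± 0.37. Both calls held without each array in turn, with a lipogenesis median of -0.61 without Burn-CLP 3. Fatty acid oxidation genes shifted downward by a median of -0.16 over 38 genes (adjusted p = 0.0058; adjusted p = 0.487 with an estimated correlation), with 0 passing either way and the call lost without Burn-CLP 2 (median -0.02, adjusted p = 0.283). Acsl5 differed by -0.60 ± 0.18, Bdh1 by -2.64 ± 0.91, Ehhadh by -1.09 ± 0.46 and Cpt1a by 0.61 ± 0.27.

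Drug metabolism and plasma protein genes were also lower as lists. Phase I genes shifted downward by a median of -0.22 over 51 genes (adjusted p = 0.00598; adjusted p = 0.463 with an estimated correlation), with 0 passing either way and the call lost without Burn-CLP 2 (median -0.06, adjusted p = 0.12), and a median of -0.14 without Sham-CLP 1 or Sham-CLP 3. Fmo1 differed by -1.76 ± 0.38, Cyp2t1 by -1.04 ± 0.26, Cyp2c11 by -2.15 ± 0.67 and Aldh3a2 by -0.71 ± 0.23. Conjugation enzyme genes shifted downward by a median of -0.17 over 34 genes (adjusted p = 0.000251; adjusted p = 0.463 with an estimated correlation), with 0 passing over all probe sets and 4 falling adjusted over the list alone. Gstm7 differed by -1.45 ± 0.36, Sult2a2 by -1.52 ± 0.39, Gstt1 by -1.59 ± 0.44 and Mgst3 by -0.85 ± 0.24, and without Burn-CLP 3 the median was -0.34. Plasma proteins known to fall in inflammation shifted downward by a median of -0.11 over 16 genes (adjusted p = 0.00899; adjusted p = 0.487 with an estimated correlation), with 0 passing over all probe sets, 3 falling adjusted over the list alone and the call lost without Burn-CLP 2 (median -0.05, adjusted p = 0.154; median -0.17 without Burn-CLP 3). Igfals differed by -3.02 ± 0.62, Serpina6 by -2.50 ± 0.63, Afm by -0.87 ± 0.25 and Igf1 by -0.44 ± 0.20. Interferon and MHC class I genes shifted downward by a median of -0.19 over 31 genes (adjusted p = 0.00672; adjusted p = 0.463 with an estimated correlation), with 0 passing either way, and this call was lost without Burn-CLP 1 (adjusted p = 0.087), with a median of -0.32 without Sham-CLP 3 or Burn-CLP 3. Psme1 differed by -0.66 ± 0.23, Psmb8 by -0.78 ± 0.28, Irf7 by -0.64 ± 0.24 and Psme2 by -0.55 ± 0.24. With the deposited scaling these 4 calls were kept, and the medians relative to all genes were -0.33 for phase I genes, -0.44 for conjugation enzymes, -0.475 for the plasma proteins and -0.18 for the interferon list.

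Markers of some other cells were higher in Burn-CLP than in Sham-CLP as lists, with calls at the preset correlation only. MHC class II presentation genes shifted upward by a median of 0.57 over 10 genes (adjusted p = 0.00598; adjusted p = 0.463 with an estimated correlation), with 0 passing either way and the call lost without Burn-CLP 3 (adjusted p = 0.0567; median 0.33 without Burn-CLP 2). RT1-DMa differed by 1.08 ± 0.37, RT1-Da by 0.83 ± 0.33, Cd74 by 0.69 ± 0.27 and Ctss by 0.54 ± 0.25; the 3 class II genes had mean signals of 314, 1060 and 1820 in Sham-Sham, 270, 661 and 981 in Sham-CLP and 624, 1232 and 1629 in Burn-CLP. Neutrophil markers shifted upward by a median of 0.34 over 10 genes (adjusted p = 0.0349; adjusted p = 0.463 with an estimated correlation), with 0 passing either way and the call lost without Sham-Sham 1, Sham-CLP 1, Burn-CLP 2 or Burn-CLP 3 (adjusted p up to 0.219). S100a9 differed by 1.29 ± 0.41, S100a8 by 0.83 ± 0.42, Alox5ap by 0.70 ± 0.27 and Cybb by 0.39 ± 0.26, whereas Lcn2 stood at 0.00 ± 0.24. Stellate cell and fibroblast markers shifted upward by a median of 0.13 over 24 genes (adjusted p = 0.0368; adjusted p = 0.487 with an estimated correlation), with 0 passing over all probe sets and 2 rising adjusted over the list alone. Mgp differed by 1.04 ± 0.20, Vim by 0.50 ± 0.19, Col1a1 by 0.54 ± 0.24 and the bright Col3a1 by -0.22 ± 0.22. The stellate call was lost without Sham-Sham 1, Sham-CLP 1, Sham-CLP 2, Burn-CLP 2 or Burn-CLP 3, with adjusted p up to 0.207 and medians of 0.03 without Sham-CLP 1, 0.22 without Sham-CLP 3 and 0.07 without Burn-CLP 2; with the deposited scaling it was kept (adjusted p = 0.0327; median 0.12 relative to all genes). Macrophage markers had a median of 0.17 (adjusted p = 0.114).

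Calls of the remaining upward shifts depended on how arrays were scaled. With the deposited scaling the median in this comparison was 0.114 over all probe sets and 0.101 over 1 probe set per gene, and list changes under it are given relative to the latter. Ribosomal protein genes had a median of 0.20 over 42 genes (adjusted p = 3.51e-06; adjusted p = 0.463 with an estimated correlation), which became -0.005 relative to all genes. Oxidative phosphorylation genes had a median of 0.16 over 41 genes (adjusted p = 0.00432; adjusted p = 0.463 with an estimated correlation), which turned to -0.06. The acute phase list had a median of 0.12 over 34 genes (adjusted p = 0.0368; adjusted p = 0.463 with an estimated correlation), which turned to -0.18. Proteasome and ubiquitin genes had a median of 0.11 over 24 genes (adjusted p = 0.0368; adjusted p = 0.567 with an estimated correlation), which turned to -0.03. Heat shock genes had a median of 0.30 over 16 genes (adjusted p = 0.00566; adjusted p = 0.463 with an estimated correlation), which became 0.16, and glucocorticoid response genes 0.27 over 17 genes (adjusted p = 0.00658; adjusted p = 0.463 with an estimated correlation), which became 0.07. All 6 calls were lost under that scaling. No member of the 6 lists (0) passed over all probe sets, and adjusted over the list alone 2 glucocorticoid response genes rose.

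Without single arrays, 4 of these 6 calls were also lost. The acute phase call was lost without Sham-CLP 1, Sham-CLP 3, Burn-CLP 2 or Burn-CLP 3 (adjusted p up to 0.318; median 0.19 without Burn-CLP 1 and 0.03 without Burn-CLP 2), and the proteasome call without Sham-Sham 1, Sham-Sham 3, Sham-CLP 3 or Burn-CLP 1 (adjusted p up to 0.565; median 0.005 without Sham-CLP 3, 0.03 without Burn-CLP 1 and 0.22 without Burn-CLP 3). The heat shock call was lost without Sham-CLP 3 or Burn-CLP 1 (adjusted p up to 0.0919) and the glucocorticoid call without Sham-CLP 3 (median 0.10, adjusted p = 0.192). Among the members, Rpl27 differed by 0.53 ± 0.15, Uqcrh by 0.42 ± 0.16, Hspe1 by 0.45 ± 0.17, Psma1 by 0.70 ± 0.19, Lbp by 0.62 ± 0.22, Sds by 1.81 ± 0.47 and the insulin-like growth factor binding protein gene Igfbp1 by 1.27 ± 0.41. In all, 16 of 34 lists shifted, 9 upward and 7 downward, 0 with an estimated correlation and 0 by fry, with a smallest fry adjusted p of 0.148. Without Burn-CLP 2 the count was 10.

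**Figure D3:**
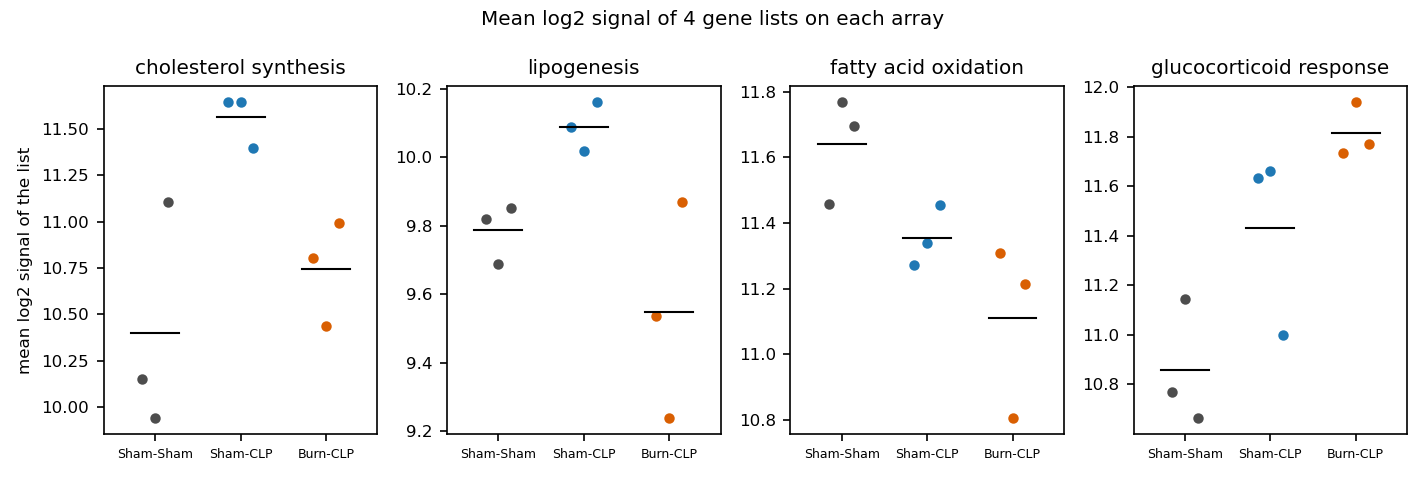
Mean log2 signal of the members of 4 gene lists on each of the 3 arrays per group, with bars at group means. Cholesterol synthesis genes lay between 11.4 and 11.6 in Sham-CLP and between 9.94 and 11.1 in the other 6 arrays.

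Changes against the shared Sham-Sham arrays were set side by side for both CLP groups. Across the 13535 probe sets, which are not independent replicates, the log2 changes had a Pearson r of 0.704 and a Spearman rho of 0.692, and 75.4% had the same sign. Simulated unchanged groups sharing these controls gave 0.502, 0.473 and 66.6%. The simulation gave all arrays the same spread for a probe set. The real Sham-Sham arrays were less alike, with mean correlations within the group of 0.886 to 0.917, than the arrays of the CLP groups (0.943 to 0.951). A wider spread in shared controls raises such values, so the simulation cannot show how much the shared controls explain. The covariance was 0.157 against 0.0417 in the simulation. All 8 probe sets called in Sham-CLP were also called in Burn-CLP, 6 higher and 2 lower, where independent lists would share 0.0195 and 0.00842 and the simulation gave 0. With 3 controls the arrays cannot be split into parts of at least 2, so how much of the excess comes from the shared controls is undecided. The count of 8 was 5 without Sham-Sham 1, 4 without Sham-Sham 2, 259 without Sham-Sham 3, 3 without Sham-CLP 1 or Sham-CLP 2, 5 without Sham-CLP 3 and 4 without Burn-CLP 3. Among the genes called in Burn-CLP, Got1 had mean signals of 3200 ± 434, 8396 ± 1923 and 16100 ± 1643, and Inhbe had 864 ± 289, 438 ± 55.0 and 153 ± 24.5 (SD) in Sham-Sham, Sham-CLP and Burn-CLP.

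Over the 3 groups, the moderated F test called 20 probe sets, with 2159 at an unadjusted p under 0.05. It called 9 without Sham-Sham 2, 303 without Sham-Sham 3 and 82 without Burn-CLP 3.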

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

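The test of RNA degradation and the permutation test of the cholesterol synthesis list were chosen after the results they bear on were seen, and the other tests of this part before. Effects against Sham-Sham differed between the CLP groups, by the test of Burn-CLP against Sham-CLP itself, for 2 genes and, at the preset correlation, 16 lists. With an estimated correlation 0 lists were called, by fry 0, and under the deposited scaling the calls of the heat shock, glucocorticoid, ribosomal, oxidative phosphorylation, acute phase and proteasome lists below were lost. Lrrc51 differed by 1.66 and Sult2b1 by 1.62 on the log2 scale, at signals near the floor in Sham-CLP. Lists with a higher median in Burn-CLP were MHC class II presentation (0.57), neutrophil markers (0.34), heat shock (0.3), glucocorticoid response (0.27), ribosomal proteins (0.2), oxidative phosphorylation (0.16), stellate cell markers (0.13), acute phase proteins that rise (0.12) and proteasome (0.11). Lists with a lower median were cholesterol synthesis (-0.81), lipogenesis (-0.4), phase I metabolism (-0.22), interferon and MHC class I (-0.19), conjugation enzymes (-0.17), fatty acid oxidation (-0.16) and plasma proteins that fall (-0.11).

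Each pair of groups gives 10 splits of its 6 arrays, too few for a share under 0.05. Real counts of called probe sets were 8, 101 and 2 for Sham-CLP against Sham-Sham, Burn-CLP against Sham-Sham and Burn-CLP against Sham-CLP, and the highest counts of other splits were 1, 1 and 1. For lists the real counts were 8, 15 and 16, and the highest of the other splits 4, 12 and 15. For the F test, 1 of 100 drawn splits of the 9 arrays, the real split, gave as many as 20 calls, and the highest other gave 5. That share is the smallest these draws can give, and it makes a random division of the arrays an unlikely source of that count. It cannot address chance differences between animals if the arrays of a group are technical.

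Sham-Sham 1 stood apart from the other 8 arrays. RNA degradation is argued against, since its beta-actin 3'/5' ratio of 1.29 lay within the range of the others, which reached 1.77. A raised signal of dim probe sets may contribute, since over the dimmer part its median signal was 100.5 against 77.5 to 94.8 for the others. Its mean correlation there was 0.499 against 0.676 to 0.747. Over the brighter part the mean correlation of Sham-Sham 1 was 0.881. The lowest other value, 0.89, belonged to Burn-CLP 2, and the remaining arrays lay between 0.926 and 0.945. Dim probe sets alone may therefore not account for it, but the gap to Burn-CLP 2 is too small to decide. No biological explanation was tested, because the labels name no difference within the Sham-Sham group.

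Cholesterol synthesis genes were highest in Sham-CLP, above both Sham-Sham and Burn-CLP. Sham-Sham 1 alone is argued against as the source, since the median change was 1.09 without it and 1.18 with it, and so is scaling, with 1.28 and -0.92 for the 2 comparisons under the deposited scaling. Brightness of the genes is argued against too, because 10000 random lists of matched signal reached at most 0.284; by the same measure Burn-CLP also lay above Sham-Sham, with a median of 0.435 against at most 0.37, though camera gave an adjusted p of 0.142. All 3 Sham-CLP arrays had higher mean list signals than the other 6 (exact two-sided permutation p = 0.0238 over 84 choices of arrays), but the list was picked from 34 for being high in Sham-CLP, so this restates the observation and leaves CLP without burn open as an explanation. Sham-Sham 3 lay at 11.1, near the lowest Sham-CLP array at 11.4, the estimated correlation removed the list's call, and food intake or time of sampling were not tested.

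Ribosomal protein and oxidative phosphorylation genes were higher in Burn-CLP than in Sham-CLP at the preset correlation, with an adjusted p of 0.463 for each list at an estimated correlation and 0 members passing. Scaling between arrays may account for this, since under the deposited scaling the medians were 0.0966 and 0.0386, below the shift of all genes of 0.101. Brightness alone is argued against for ribosomal proteins, whose median of 0.196 stood at percentile 100 of 10000 matched random lists, above their maximum of 0.181. For oxidative phosphorylation the median of 0.157 stood at percentile 99.91, while most matched random lists lay between -0.132 and 0.091. This argues against brightness alone there too. The rule set beforehand asked for a median beyond all 10000 lists, which was not met, because a few reached the same size.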

How the results depend on the processing

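Named genes that passed kept their direction in the alternatives followed gene by gene, which leave out fits of only 2 groups. In these, 3 of 8, 5 of 29 and 0 of 2 named calls always held, with 16 alternatives for Ntf3 and 17 for the others that held, for Sham-CLP against Sham-Sham, Burn-CLP against Sham-Sham and Burn-CLP against Sham-CLP. Counts of calls moved far more, and the causes were not tested except where fewer arrays or probe sets are the alternative itself. In the order of those comparisons, the main counts were 8, 101 and 2, with 20 for the F test and 8 called in both CLP groups. The deposited scaling gave 4 and 1 for the first and last, 4 called in both and 16 shifted lists in Sham-CLP. A floor at the 5th percentile gave 44 and 1 for the Burn-CLP comparisons and 5 in both; at the 40th percentile it gave 17 for Burn-CLP against Sham-CLP, 40 for the F test and 3 in both. Without a filter the last comparison gave 4 and the F test 40, and with 6 arrays above the 40th percentile Burn-CLP gave 204 against Sham-Sham and 0 against Sham-CLP, the F test 33, with 5 in both. Array weights gave 69, 262 and 47, 151 for the F test and 39 in both. A trend and robust prior gave 317 and 10 for the Burn-CLP comparisons and 127 for the F test. Fits of only the 2 groups compared gave 13 and 0 for Burn-CLP. An estimated correlation left 0, 0 and 0 shifted lists.

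The replicate number as a block gave 4, 59 and 0 calls and 3 in both. Residuals of same-numbered arrays correlated between -0.0261 and 0.0806 over 9 pairs, and those of other pairs between -0.0725 and 0.0366. Of the same-numbered pairs, Sham-CLP 3 with Burn-CLP 3 (0.077) and Sham-Sham 3 with Sham-CLP 3 (0.0606) lay above every pair with different numbers. So did Sham-Sham 1 with Sham-CLP 1 (0.0806) and Sham-CLP 2 with Burn-CLP 2 (0.0561). Sham-Sham 2 did so with Burn-CLP 2 (0.045) and with Sham-CLP 2 (0.0394). Sham-Sham 3 with Burn-CLP 3 (0.0144) did not. Sham-Sham 1 with Burn-CLP 1 (-0.0261) and Sham-CLP 1 with Burn-CLP 1 (-0.00963) were negative. Most same-numbered pairs thus lay above all others, but all values are small and the ranges overlap. Whether the numbers pair the arrays is undecided, and the main fit left such pairing out.

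With 1 array left out, counts ran from 4 to 347, 19 to 645 and 0 to 36, from 9 to 303 for the F test and from 3 to 259 in both. Lists ran from 4 to 9 in Sham-CLP and from 10 to 16 between the CLP groups. Chosen after seeing the data, calls with no array of the compared groups at the floor numbered 4, 61 and 0, and the deposited scaling without Sham-Sham 1 gave 5 and 28 against Sham-Sham. Of the 101 calls in Burn-CLP, 24 were shared without Sham-Sham 1, 98 without Sham-Sham 3 and 83 with the deposited scaling. Floors at the 5th and 40th percentile shared 37 and 24, no filter 49 and the stricter filter 64. The replicate block shared 51, array weights 100, the trend and robust prior 95 and the fit of only 2 groups 12. For Sham-CLP the fit of only 2 groups also called 8 but shared 4, so similar counts need not mean the same genes. Between the CLP groups the deposited scaling reversed the acute phase list (-0.0794) and, relative to all genes, oxidative phosphorylation (0.0386, or -0.063). The proteasome and ribosomal protein lists lost their calls without a reversed test direction. Their medians relative to all genes were -0.032 and -0.005. Signal near the floor limits fold changes of dim genes.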

Other observations

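The permutation test and RNA test above apart, the tests of this part were set before their results were seen, with these exceptions. For the growth hormone list only Burn-CLP against Sham-Sham was set beforehand. The genes in the next paragraph were chosen after their results were seen.

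Beyond the genes above, the following single genes were called in Burn-CLP liver against Sham-Sham, with no test of a common function. Eif4ebp3, an inhibitor of translation initiation, rose by 2.43 ± 0.32 on the log2 scale (n = 3 per group, adjusted p = 0.0192), and the stress gene Sesn1 by 1.92 ± 0.32 (adjusted p = 0.0357). The amino acid transporter gene Slc38a4 rose by 1.22 ± 0.17, the glycolytic Aldoa by 1.13 ± 0.20, the survival gene Mcl1 by 1.15 ± 0.20 and the decorin gene Dcn by 1.48 ± 0.21. Lower were the hepatic lipase gene Lipc (-1.63 ± 0.27), the glycerol phosphate dehydrogenase gene Gpd1 (-1.25 ± 0.22), Phgdh of serine synthesis (-1.56 ± 0.29), Alad of heme synthesis (-1.56 ± 0.26) and the mannose-binding lectin gene Mbl2 (-0.98 ± 0.18).

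Other lists had no called shift in any comparison with the main scaling. Their medians in Burn-CLP against Sham-Sham were 0.002 for gluconeogenesis (adjusted p = 0.467), -0.06 for glycolysis (0.925), 0.06 for the tricarboxylic acid cycle (0.705), -0.13 for bile acids (0.306), -0.15 for antioxidant genes (0.496) and 0.17 for cytokines, chemokines and NF-kappaB targets (0.823). They were -0.07 for endothelial markers (0.92), 0.04 for bile duct markers (0.823), -0.27 for red cell transcripts (0.149), 0.08 for cell cycle genes (0.688), 0.04 for complement and coagulation (0.641) and -0.13 for the growth hormone, insulin-like growth factor and insulin axis (0.82). Among lists called in another comparison but not in this one, lymphocyte markers had a median of -0.15 (0.406), heat shock genes of 0.18 (0.149), MHC class II genes of 0.26 (0.142) and stellate cell markers of -0.03 (0.762). Mean and test went the other way from the median for endothelial, bile duct and stellate cell markers.

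Igfals, known to depend on growth hormone in rat liver, fell in Burn-CLP against Sham-Sham, and Cyp2c11, also known to depend on it, had a lower mean signal without passing (adjusted p = 0.0538). A hypothesis is that growth hormone action may be lower in that group. Among 17 other genes known to depend on it, chosen without those seen before, the median log2 change against Sham-Sham was -0.17, at percentile 7.88 of 10000 random lists of matched signal, which leaves the hypothesis undecided. The median treats every gene as falling when growth hormone action falls, which was not checked for each gene. Against Sham-CLP, in a comparison made afterwards, the median was -0.38, below all 10000 random lists, whose lowest was -0.36. Genes of the random lists were drawn independently. Their spread does not allow for members that move together, so ranks among them are not p-values. For Sham-CLP against Sham-Sham, for which no prediction was set beforehand, the median was 0.12, at percentile 93.64. Which of the 2 groups moved is therefore undecided as well. Members went both ways in Burn-CLP against Sham-Sham, with -1.04 for the growth hormone receptor gene Ghr and -1.69 for Mup5 but 0.67 for the hormone's target Cish and 0.83 for Egfr, genes chosen after their values were seen.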
